A study of Drosophila melanogaster with 2 samples.

How the data were processed

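Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on testes of Drosophila melanogaster carrying mutations in both E(z) and bam. E(z) encodes a Polycomb group histone methyltransferase, and bam (bag of marbles) is needed for spermatogonia to stop dividing and enter differentiation, so that bam mutant testes fill with spermatogonia-like germ cells. Per the labels' protocols, flies with the E(z)61 allele were kept at 29 °C for the last 3 days before eclosion, 200 pairs of testes were used per immunoprecipitation, and the tissue was fixed with formaldehyde at 37 °C for 15 min. Chromatin was sheared to about 200 bp, libraries were amplified for 17 PCR cycles, and fragments near 220 bp were taken from a gel and read on a Solexa 1G instrument. There was 1 library for trimethylation of lysine 4 of histone H3 (H3K4me3), a mark found at the promoters of active genes, and 1 library for RNA polymerase II (Pol II).

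The authors deposited, for each library, the list of its mapped tags. Every tag was 25 bp long and had a chromosome, a start, an end, a strand and 1 of the codes U0, U1 and U2. The deposited score column was 0 in every row of both files and was not used. The genome builds named in the submitters' processing notes are dm3 and BDGP5, and coordinates are given on dm3, counted from 1. The aligner, its limit on mismatches and any filter on tags are not given in the sources used here. The H3K4me3 file held 4800665 tags and the Pol II file 5040020.

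Many tags shared a position and strand, and only 2334281 positions of the H3K4me3 library (48.6% of its tags) and 2725302 of the Pol II library (54.1%) were distinct. Of each set of tags with the same position and strand, 1 was kept, because repeats after 17 PCR cycles cannot be told from independent fragments. The 5′ end of each tag was moved 75 bp downstream, toward the middle of its fragment. The 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X were analysed, with 2276303 H3K4me3 and 2640732 Pol II positions. These positions are called tags from here on.

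The tags were counted in 1 kb bins and in 200 bp bins. Background was the median tag density of a chromosome arm over 5 kb bins holding a tag in either library, so that the single X of males was measured against itself. A bin was called enriched when its count was at least 3 times background and its Poisson upper tail, adjusted by the Benjamini-Hochberg method over the bins of that library, was at most 0.001. That tail served as a threshold within a library and is not a test between conditions. Enriched 200 bp bins were joined over gaps of up to 400 bp into regions. Regions overlapped when they shared at least 1 bp. Chance overlap was measured by rotating the Pol II regions along each arm 100 times. At this depth a 200 bp bin had to reach 7.14-fold for H3K4me3 and 3.92-fold for Pol II on 2L, and 8.82-fold and 5.00-fold on X, since small counts do not pass the Poisson threshold. The calls were tested on simulated libraries of 120368 bins of 1 kb. Their tags were placed at random at the background rate of each arm, and 50 windows were raised by each known fold. At 5-fold, 88% of the H3K4me3 windows and 100% of the Pol II windows were called as 1 kb bins, and at 3-fold 28% and 58%. As regions, 20% of H3K4me3 and 96% of Pol II windows were found at 5-fold, and 92% and 100% at 10-fold. The adjusted threshold depends on the number of enriched bins, and the simulated libraries held far fewer of these than the real ones. It was therefore stricter in the simulation, and the shares found can be lower than those in the real libraries. No bin or region outside the windows was called in either simulated library. The simulated background follows the same Poisson model as the threshold, so this does not measure false calls on the real background, which need not be even.

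Intervals are 95% intervals. They are exact Poisson for a fold, exact Clopper-Pearson for a share, exact conditional for a ratio of both counts and from 1000 bootstrap draws over bins or regions for ratios of X to autosomes. They cover counting error only, since there was 1 library per antibody and tags carry no molecular identifiers. Bins and regions are not replicates, so no p-value between groups is given. A ratio of Pol II to H3K4me3 folds was ranked with 0.5 tag added to each count, and a count of 0 was taken to allow up to 3 tags. No input library entered the calculations. The series design sets these testes against bam single mutant testes, whose libraries belong to another series and were not analysed here, so no comparison of genotypes was made.

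The bins and regions named were fixed by rule before the data were examined: the 10 bins with the highest fold for each antibody, the 10 highest and 10 lowest ratios of Pol II to H3K4me3 among enriched bins, and the 5 longest regions and the 5 with the most tags for each antibody. Promoters, gene lists, named genes and the ratio of Pol II at promoters to that in gene bodies had been planned as well. The gene annotation at hand is of Release 6 of the genome, a different build from that of the tags, so no position was assigned to a gene, and bins of the genome took the place of promoters. Alternatives that were run were all tags kept, no move or a move of 110 bp, thresholds of 2-fold and 5-fold, 1 mean background for all arms, both libraries thinned to the same number of tags, background bins of 1 kb and 20 kb, no joining over gaps, and an overlap of at least 0.5 of the shorter region. Tags of code U0 alone, and autosomes thinned to the density of the X, were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.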

Results

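H3K4me3 and Pol II were mapped in testes of the E(z)61 bam double mutant, with 1 library per antibody and no replicates. The study asked how H3K4me3 and Pol II are placed with mutant E(z) in testes filled with spermatogonia-like cells. Loss of E(z) activity was not measured here. With 1 genotype at hand, the comparison made here is between both antibodies within that tissue. The H3K4me3 library held 4800665 tags and the Pol II library 5040020, of which 2276303 and 2640732 were distinct positions on the chromosome arms. Every fold is over the background of its own chromosome arm, and intervals cover counting error only.

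A larger share of the H3K4me3 tags than of the Pol II tags fell into enriched regions. Regions enriched for H3K4me3 numbered 8011, covered 11.8 Mb or 9.82% of the arms, and held 71.3% of the H3K4me3 tags. Regions enriched for Pol II numbered 12138, covered 7.10 Mb or 5.90% of the arms, and held 27.1% of the Pol II tags. The median H3K4me3 region was 800 bp long and reached 12.5-fold over background, and the median Pol II region was 400 bp long and reached 5.00-fold. The tag density inside regions was 137 per kb for H3K4me3 and 101 per kb for Pol II. Background was about 3 times higher in the Pol II library, at 16.6 to 19.6 tags per kb on 2L, 2R, 3L and 3R against 5.6 to 6.7 for H3K4me3, and without an input library it was not divided into bound and unspecific tags.

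The broadest H3K4me3 domain lay on 2L from 4964401 to 4982800. It was 18.4 kb long, held 3396 tags, the most of any H3K4me3 region, and stood at 33.0-fold (31.9 to 34.1). Within it H3K4me3 formed a series of separate peaks, and Pol II stood at 3.42-fold (3.21 to 3.63) over the whole domain. The next longest domains were 15.6 kb on 3L from 6734201 to 6749800, 14.2 kb on 3L from 16572201 to 16586400, 14 kb on X from 1352001 to 1366000 and 13.8 kb on 2L from 6955601 to 6969400. Their H3K4me3 was between 20.5-fold and 33.6-fold, and Pol II over the same stretches was between 3.13-fold and 3.51-fold. The domains on 3R from 7038601 to 7051200, with 2623 tags, on 3L from 9444001 to 9457200, with 2441 tags, and on 3R from 1288001 to 1301400, with 2355 tags, completed the 5 with the most H3K4me3 tags. Each of these 8 domains overlapped a Pol II region. With 101 Pol II regions per Mb of the arms, stretches this long would often overlap one by chance, and a chance share for this length was not measured. Their folds depend on the background, and with 1 mean background for all arms H3K4me3 was 9.76-fold in the longest domain and 5.36-fold to 11.01-fold over the 8.

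The strongest Pol II sites were on 3L and 3R and were not the sites of the strongest H3K4me3. The bin with the most Pol II, on 3R from 19881001 to 19882000, held 648 tags at 34.8-fold (32.2 to 37.6), while its H3K4me3 was 6.83-fold (4.90 to 9.27). It belonged to a Pol II region of 4.6 kb from 19879601 to 19884200 at 19.1-fold. On 3L the bin from 9369001 to 9370000 reached 31.5-fold and the bin from 9377001 to 9378000 reached 29.3-fold, with H3K4me3 at 14.5-fold and 32.8-fold. On 3R the bin from 17123001 to 17124000 reached 24.7-fold, within a region of 3.4 kb from 17121801 to 17125200 at 19.7-fold. The Pol II region with the most tags lay on 3L from 3192401 to 3199600, with 1671 tags over 7.2 kb at 13.0-fold (12.4 to 13.7). There Pol II filled the middle of the region. The highest H3K4me3 inside it lay near the right end, and another H3K4me3 peak lay just outside the left end. Of the 10 bins with the most Pol II, 5 were on 3L, 4 on 3R and 1 on 2L. The bin on 2L, from 12007001 to 12008000, had Pol II at 22.1-fold and H3K4me3 at 2.5-fold (1.37 to 4.19). The longest Pol II regions were 8.8 kb on 2R from 8056001 to 8064800 and 8.4 kb on 3L from 13469601 to 13478000. No gene was assigned to any of these positions. The tissue had been fixed at 37 °C for 15 min, a temperature that induces the heat shock response in flies, and any Pol II recruited during fixation was not separated from that of the living tissue.

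**Figure D1:**
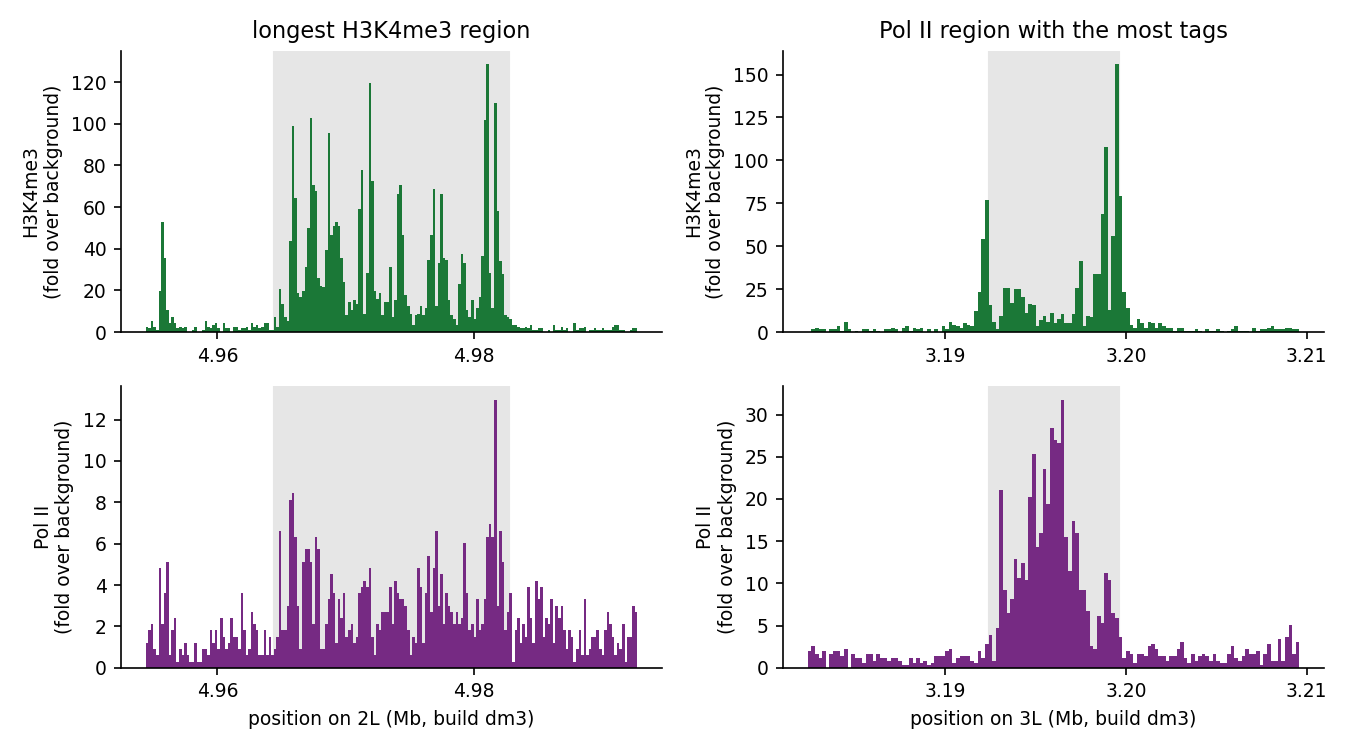
H3K4me3 (upper panels) and Pol II (lower panels) as fold over background in 200 bp bins, at the longest H3K4me3 region (left, position on 2L in Mb) and the Pol II region with the most tags (right, position on 3L in Mb), each shaded grey with 10 kb on either side. The region on the left spans 18.4 kb with Pol II at 3.42-fold, and on the right Pol II peaks between the H3K4me3 peaks.

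The highest H3K4me3 folds in 1 kb bins were 102-fold (91.3 to 113) on X from 1376001 to 1377000, 98.8-fold on X from 19373001 to 19374000 and 98.4-fold on 2L from 10201001 to 10202000. Pol II in these bins was 7.91-fold, 4-fold and 8.73-fold. Of the 10 highest bins 9 were on X, but this rests on the low background of X, 3.4 tags per kb. Those 9 bins held 305 to 346 tags, fewer than the 551 of the bin on 2L, and with 1 mean background for all arms 0 of the 10 highest bins were on X. Under that background the 3 bins above stood at 18.3-fold, 17.8-fold and 29.1-fold. The 10 highest Pol II bins were the same under both backgrounds.

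Bins with more H3K4me3 had more Pol II. Of 115685 bins with a tag, 19004 (16.4%) were enriched for H3K4me3 and 9069 (7.84%) for Pol II. Both marked 7081 bins, 4.75 times the 1490 of independent sets. H3K4me3 was found in 78.1% (77.2 to 78.9) of the Pol II bins, and Pol II in 37.3% (36.6 to 38.0) of the H3K4me3 bins. Median Pol II was 0.73-fold in bins under 1-fold H3K4me3, 1.91-fold at 3 to 5-fold, 3.02-fold at 20 to 40-fold and 4.55-fold at 60-fold or more. The share enriched for Pol II went from 0.402% (0.351 to 0.459) in the lowest class to 89.7% (86.7 to 92.2) in the highest, which held 496 bins. Spearman's rho across bins, which are not independent replicates, was 0.631. In the reverse direction the relation was flat at the top. Median H3K4me3 was 3.24-fold in bins with Pol II at 2 to 3-fold, 9.33-fold at 3 to 5-fold, 14.8-fold at 5 to 10-fold and 15.3-fold at 10-fold or more. The counts of Pol II bins depend on the threshold, with 18935 at 2-fold and 2671 at 5-fold, and so does the share of H3K4me3 bins with Pol II, 63.6% at 2-fold and 15.1% at 5-fold. The share of Pol II bins with H3K4me3 was 65.6% at 2-fold and 77.7% at 5-fold, so at 2-fold both shares were close to each other. Bins with both numbered 12417 at 2-fold and 2076 at 5-fold. With 1 mean background for all arms, 8593 bins were enriched for H3K4me3, 4976 for Pol II and 2842 for both.

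**Figure D2:**
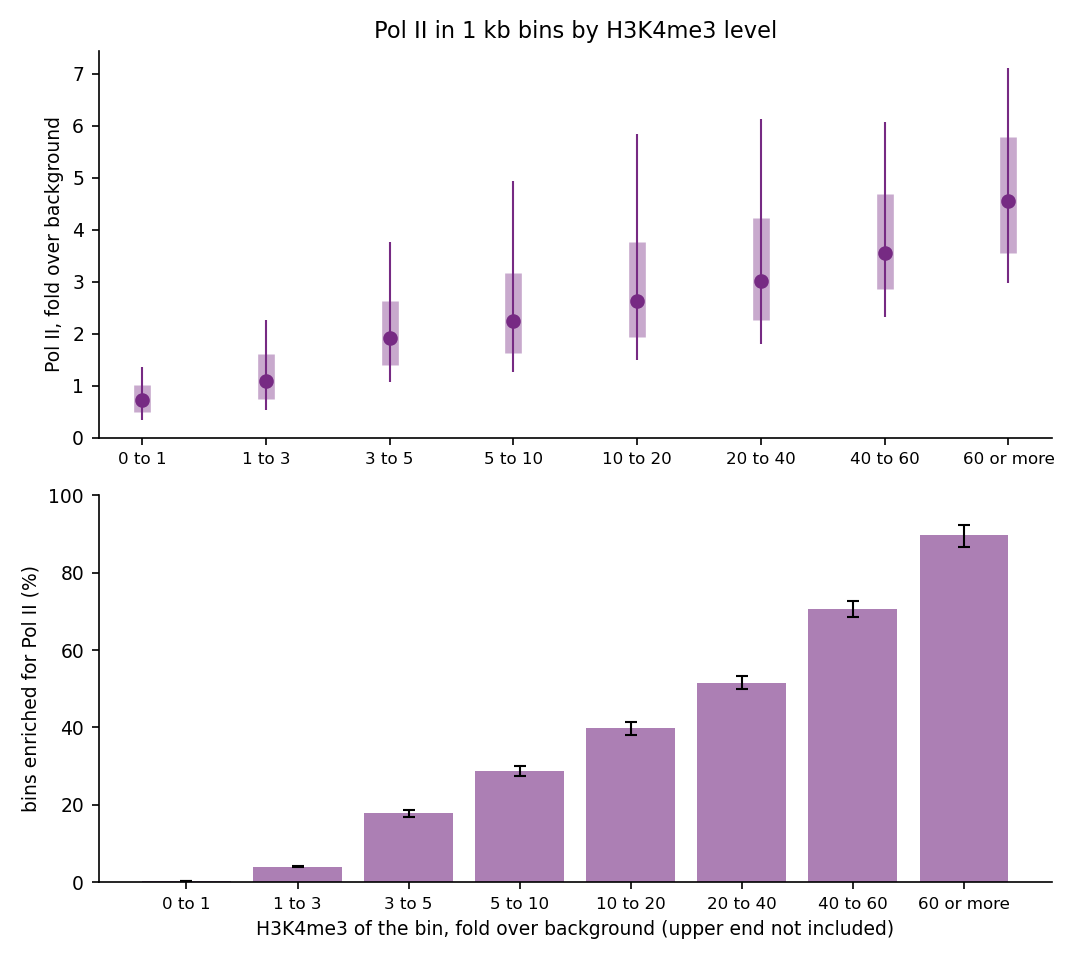
Pol II in 1 kb bins grouped by H3K4me3 fold over background (horizontal axis of both panels). Above, points are median Pol II fold, thick bars the 25th to 75th percentile and thin lines the 10th to 90th percentile; below, bars are the percent of bins enriched for Pol II with exact 95% intervals, from 0.402% in the lowest class to 89.7% in the highest.

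Regions gave the same relation. Of the H3K4me3 regions 60.5% (59.4 to 61.5) overlapped a Pol II region, and of the Pol II regions 51.6% (50.7 to 52.5) overlapped an H3K4me3 region. Rotated Pol II regions gave means of 16.8% and 13.3%, and no more than 18.0% and 14.4% in 100 rotations. Long regions overlapped more often, with 3509 of the 3957 H3K4me3 regions of 1 kb or more (88.7%) and 1953 of the 2217 Pol II regions of that length (88.1%). Rotation gave means of 24.6% and 18.9% for these lengths, and no more than 26.4% and 22.0%. The 3168 H3K4me3 regions without a Pol II region were short, with a median of 200 bp against 1600 bp for the others, and Pol II in them was 1.82-fold. The 5876 Pol II regions without an H3K4me3 region had a median of 200 bp and 4.66-fold Pol II, with H3K4me3 at 2.08-fold against 19.0-fold in the overlapping ones. In both groups the low fold of the other antibody follows in part from the grouping itself. Absence of an H3K4me3 region is not absence of the mark, since a 200 bp bin needed 5.43-fold to 8.82-fold H3K4me3, depending on the arm, to be called. With all tags kept, the counts rose to 16524 H3K4me3 and 20317 Pol II regions, and 42.2% and 46.9% overlapped.

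Around the summits of 6261 Pol II regions that overlapped H3K4me3, H3K4me3 was highest close to the summit and declined over about 1 kb. The mean was 28.6-fold at 200 bp on either side, 20.2-fold at 500 bp and 12.9-fold at 1000 bp, and 10.2-fold beyond 1500 bp. At 100 bp it dipped to 24.9-fold on one side and 25.2-fold on the other, and a single 50 bp bin at the summit stood at 31.3-fold. Pol II was much narrower. It fell from 14.5-fold at the summit, a height raised by choosing the highest bin as the summit, to 3.82-fold at 200 bp. Around 5875 Pol II summits without an H3K4me3 region, H3K4me3 was 2.75-fold in the single 50 bp bin at the summit. It was 2.38-fold and 2.36-fold in the bins 50 bp to either side and 2.35-fold at 500 bp, and rose to 4.35-fold at 2000 bp. Low H3K4me3 near these summits follows in part from choosing Pol II regions that overlap no H3K4me3 region. The rise takes in neighbouring H3K4me3 regions, since 28.9% of such Pol II regions lay within 1 kb of one and 36.1% at 1 to 5 kb.

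**Figure D3:**
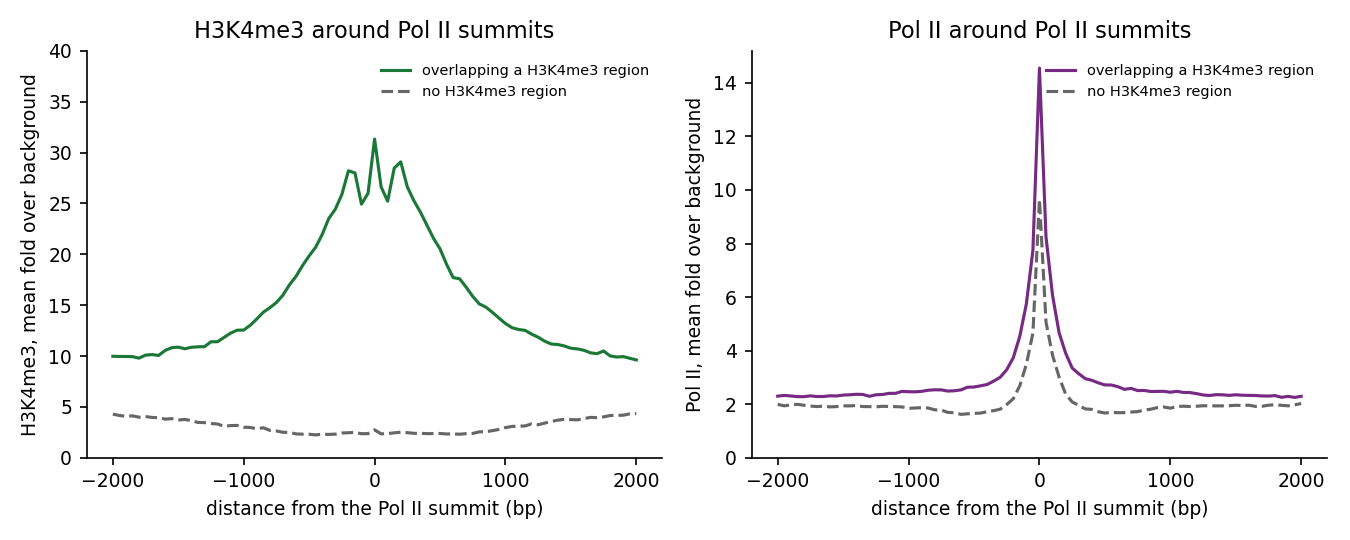
Mean H3K4me3 (left) and Pol II (right) fold over background in 50 bp bins against the distance in bp from the Pol II summit, for Pol II regions that overlapped an H3K4me3 region (solid, 6261) and for those that did not (dashed, 5875). H3K4me3 stands at 28.6-fold 200 bp from the summit in the solid line and stays under 5-fold in the dashed line. The groups were split by H3K4me3 regions, so part of this difference follows from the grouping.

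Single bins lay far from the common relation in both directions. They were picked as the extremes among all enriched bins, and the intervals below do not allow for that choice. The 10 enriched bins with the highest Pol II relative to H3K4me3, ranked with 0.5 tag added to each count, had 0 to 3 H3K4me3 tags. Of these 4 were on X and had no H3K4me3 tag and 33 to 40 Pol II tags, where 33 was the fewest in any called bin of X. The exact lower limit of their ratio of folds was 2.61 to 3.20. The limit was higher in the other 6 bins, and highest in 2 of 2L. On 2L the bin from 15911001 to 15912000 had 175 Pol II tags at 10.5-fold (9.04 to 12.2) and 3 H3K4me3 tags, a ratio of 19.7 (6.62 to 96.3). The bin on 2L from 16283001 to 16284000 had 90 Pol II tags and 1 H3K4me3 tag, a ratio of 30.4 (5.31 to 1212). At the other end, H3K4me3 stood at 42.6-fold (36.0 to 50.2) on X from 13054001 to 13055000 with Pol II at 0.73-fold (0.31 to 1.43). On 3L from 11068001 to 11069000 H3K4me3 was 20.7-fold with Pol II at 0.51-fold (0.23 to 0.96), and on 3R from 6232001 to 6233000 it was 33.5-fold with Pol II at 0.91-fold (0.53 to 1.46). In the bin with the lowest ratio, on 2L from 11993001 to 11994000, there were 30 H3K4me3 tags and 1 Pol II tag. The 10 highest ratios lay between 3.74 and 4.65 and the 10 lowest between -5.91 and -5.14 on the log2 scale with 0.5 tag added. These values and the folds on X rest on the background of each arm, and with 1 mean background the ratios of the same bins lay between 5.10 and 6.13 and between -4.56 and -3.66.

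The X of these male tissues had fewer tags than the autosomes with both antibodies. Background on X was 3.4 H3K4me3 tags per kb and 11 Pol II tags per kb. Relative to the pooled 2L, 2R, 3L and 3R this was 0.567 (0.567 to 0.621) for H3K4me3 and 0.611 (0.593 to 0.633) for Pol II, above the 0.5 of 1 X to a pair of autosomes. With 1 kb bins the H3K4me3 ratio was 0.667, on counts of few tags per bin. Inside regions of 1 kb or more, the ratio of tag densities was 0.649 (0.612 to 0.680) for H3K4me3 and 0.728 (0.692 to 0.766) for Pol II. These values depend on the higher fold that X regions needed to be called, and when the autosomes were thinned to the X background they were 0.60 and 0.580. Regions enriched for H3K4me3 covered 10.0% of X and between 8.87% and 11.4% of the large autosome arms, and Pol II regions covered 4.46% of X and between 5.79% and 6.56% of those arms. In 1 kb bins the order for Pol II was the opposite, with 9.53% of the bins of X enriched and 7.21% to 7.88% of those of the large autosome arms. A 200 bp bin needed 5.00-fold Pol II on X to be called and 3.76-fold to 3.93-fold on those arms.

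**Figure D4:**
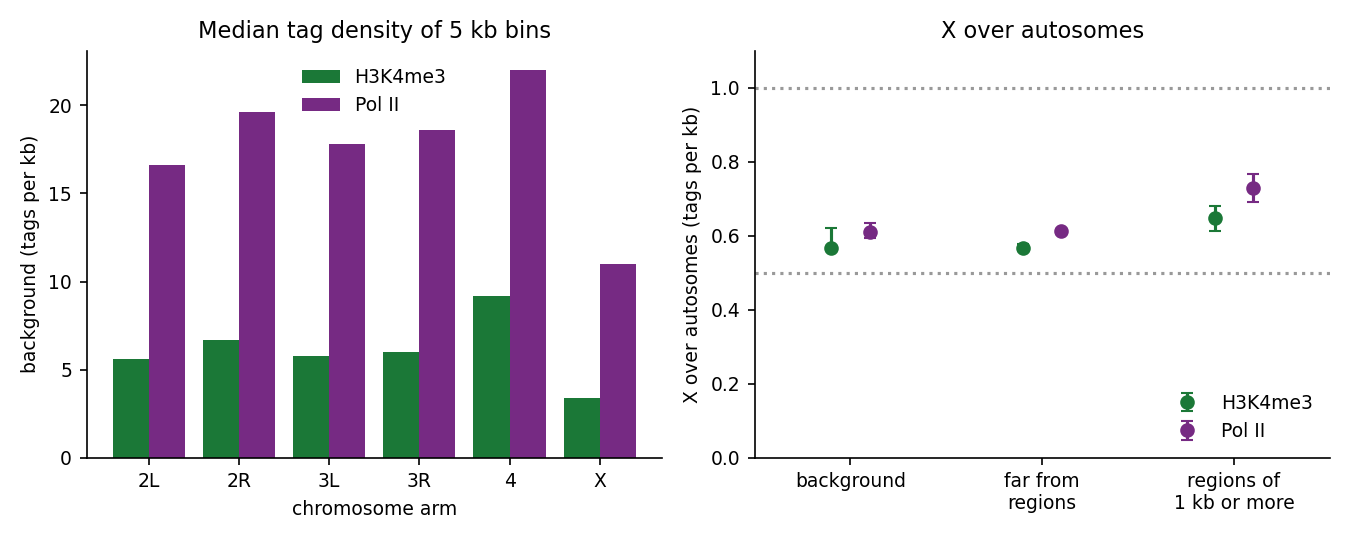
Left, background as tags per kb (median 5 kb bin) of each chromosome arm for H3K4me3 and Pol II; right, density on X over that on 2L, 2R, 3L and 3R for background, for 1 kb bins at least 5 kb from any region and for regions of 1 kb or more, with 95% bootstrap intervals. Dotted lines mark 0.5 and 1, and background lies at 0.567 for H3K4me3 and 0.611 for Pol II.

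The small chromosome 4, much of which is packaged as heterochromatin, had the highest background of the arms, with 9.2 H3K4me3 and 22 Pol II tags per kb. It held 97 H3K4me3 regions covering 7.19% of its length and 111 Pol II regions covering 3.63%. The median of its 46 H3K4me3 regions of 1 kb or more was 15.0-fold, and on the other arms the medians lay between 22.5-fold and 29.3-fold. In tags per kb these regions of 4 were closer to the large autosome arms, at 138 against 151 to 158. Of the H3K4me3 regions on 4, 60.8% (50.4 to 70.6) overlapped a Pol II region, within the counting error of the 60.5% over all arms.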

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

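Tags on sequences outside the chromosome arms were not part of the comparisons above and stood above the 3 tags that a count of 0 allows in both libraries. The mitochondrial genome had 86 distinct H3K4me3 positions and 463 Pol II positions, a ratio of Pol II to H3K4me3 of 5.38 (4.27 to 6.86), against 2.93 for autosomal bins at least 5 kb from any region. That value leaves out enriched regions, while the counts given here are of whole sequences. Over the whole arms, enriched regions included, there were 2276303 H3K4me3 and 2640732 Pol II positions, a much lower ratio than 2.93. Unplaced sequence (U) had 25607 H3K4me3 and 37660 Pol II positions, a ratio of 1.47. The heterochromatic sequences had 1896 and 1758 on 2LHet, 11251 and 16149 on 2RHet, 9544 and 13820 on 3LHet, 8005 and 12768 on 3RHet, and 1089 and 1080 on XHet, H3K4me3 first. The Y sequence (YHet) had 500 H3K4me3 and 872 Pol II positions. The ratio was 0.93 on 2LHet and 0.99 on XHet, and 1.44, 1.45, 1.60 and 1.74 on 2RHet, 3LHet, 3RHet and YHet. No biological explanation was tested for these counts.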

How the results depend on the processing

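With 1 library per antibody no library could be left out, and no paired analysis was possible because no groups share replicates. Windows at transcription start sites, gene bodies and gene lists were not run, for want of an annotation on the build of the tags. Tags of code U0 alone and the thinning of autosomes to the X were chosen after seeing the data. Not every result was run under all settings that enter it. The X to autosome background was run only with all tags kept and with background bins of 1 kb and 20 kb. Its ratio inside regions was run only with thinned autosomes. Those background bins and the thinned autosomes were used for no other result. Values outside 1.5 times a main count, or outside the interval of a share or ratio, were these. Bins enriched for H3K4me3 numbered 8593 with 1 mean background, which counts the bound tags as background. Bins enriched for Pol II numbered 18935 at 2-fold, 2671 at 5-fold and 4976 with 1 mean background, and bins enriched for both 12417, 2076 and 2842. Pol II marked 63.6%, 15.1% and 33.1% of H3K4me3 bins under those settings, 36.6% at equal depth and 39.9% with code U0. H3K4me3 marked 65.6% of Pol II bins at 2-fold, 57.1% with 1 mean background and 76.6% with code U0. Spearman's rho was 0.602 with all tags, 0.657 with 1 mean background, 0.625 at equal depth and 0.622 with code U0. All tags gave 16524 H3K4me3 and 20317 Pol II regions, and no joining gave 13121 H3K4me3 regions. H3K4me3 regions overlapping Pol II were 42.2% with all tags, 63.6% with no move, 62.1% with a move of 110 bp, 49.9% at 5-fold, 62.8% with 1 mean background, 59.1% at equal depth, 47.8% with no joining and 58.5% with an overlap of 0.5 of the shorter region. Pol II regions overlapping H3K4me3 were 46.9% with all tags, 54.3% with no move, 60.6% at 5-fold, 44.2% with 1 mean background, 52.8% at equal depth and 49.8% with the longer overlap. The X to autosome background of H3K4me3 was 0.667 with 1 kb bins, and the ratio inside regions was 0.60 for H3K4me3 and 0.580 for Pol II with thinned autosomes. Apart from these constructions the cause was not tested. Of 57 further values, which are the named bins and regions and the number of long stretches without H3K4me3, 29 left their counting interval or 1.5 times range with all tags, 45 with 1 mean background, 23 with code U0, 1 with a move of 110 bp, 1 at equal depth and 0 with no move. The other settings were not run on the named bins and regions. The bins and regions named by rule kept their direction under the settings run, with the highest ratios of Pol II to H3K4me3 no lower than 2.88 and the lowest no higher than -3.66 on the log2 scale. Regions picked later, in the other observations, were not run under other settings. Of simulated 5-fold windows, 20% were found as regions for H3K4me3 and 96% for Pol II. The simulated libraries held few enriched windows, so the adjusted threshold was stricter there than in the real libraries.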

Other observations

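Long parts of the arms had no H3K4me3 region. There were 185 stretches of 100 kb or more without one, together 27.2 Mb or 22.6% of the arms. Median Pol II over these stretches was 0.72-fold and median H3K4me3 0.73-fold. This is near the level of region-free sequence in general, since background includes bound bins. Bins at least 5 kb from any region on the large autosome arms had a mean of 4.53 H3K4me3 tags per kb against a background of 6, and 13.3 Pol II tags against 18. They held 17.0 Pol II regions per Mb against 48.8 per Mb over the arms for Pol II regions without an H3K4me3 region, the only kind these stretches can hold. Of the stretches, 35 had no Pol II region. The longest ran on 2L from 17502201 to 17963400, 461 kb with 3 Pol II regions, and on 2L from 15771201 to 16231800, 461 kb with 9 Pol II regions, the strongest at 10.5-fold. In 11 of the stretches over 20% of the 1 kb bins held no tag in either library. Chromosome 4 had 0 such stretches. Their number depends on the repeats of tags, since with all tags kept it was 8, while the other settings gave 185 to 266; the cause was not tested.

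Of the tests that follow, those of weak H3K4me3, of unevenness shared by both libraries, of bound chromatin in background bins, of a shared side and of uneven tag density were chosen after their results had been seen. The regions named in the next paragraph were likewise picked after their values were seen.

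Several strong Pol II regions had no H3K4me3 region on them. On 2L from 12010001 to 12012600 Pol II held 621 tags at 14.4-fold (13.3 to 15.6) with H3K4me3 at 2.20-fold (1.5 to 3.10). On 2L from 20821601 to 20824400 Pol II was 9.60-fold and H3K4me3 1.08-fold (0.63 to 1.74), and on 2L from 15910801 to 15914000 Pol II was 7.55-fold and H3K4me3 0.95-fold (0.55 to 1.52), 140 kb from the nearest H3K4me3 region. The region on 2L from 12010001 touches an H3K4me3 region. Of the 10 such regions with the most Pol II tags 6 were on 2L, and H3K4me3 in the 10 was between 0.95-fold and 2.99-fold. Over all 5876, 28.9% lay within 1 kb of an H3K4me3 region, 36.1% at 1 to 5 kb and 35.0% farther away.

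The values argue against chance clusters of tags as the source of the stronger Pol II regions without H3K4me3. On a random part of the Pol II tags, 2923 regions of this kind were called, with a median of 7.14-fold in that part. Their median in the other part was 5.36-fold. A call on fewer tags needs a higher fold. The weaker of the 5876 regions, whose median was 4.66-fold, were therefore not tested. Copy number or mappability raise both libraries alike, so that the H3K4me3 fold would equal the Pol II fold. In 3784 regions chosen on random parts of both libraries and measured in the other parts it was 0.523 (0.504 to 0.540) of it. This argues against unevenness as the source of those 3784 as a set, but not of single regions. In 18.9% of all 5876 regions H3K4me3 within 500 bp had a lower limit above 2-fold. Weak H3K4me3 under its own threshold may account for these. The 500 bp on either side can also reach into a called H3K4me3 region nearby, so this does not show weak H3K4me3 on the region itself. For 17.0% the upper limit of that fold was below 2-fold. This does not exclude weak H3K4me3 on the region itself, since the fold is a mean that takes in 500 bp on either side. Counting error alone also puts some regions into either class. For the other 64.1% the counts were too few to decide. No biological explanation was tested.

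The X background stood above 0.5 of the autosomes in both libraries. In bins at least 5 kb from any region the ratio was 0.568 (0.559 to 0.578) for H3K4me3 and 0.612 (0.604 to 0.619) for Pol II. Called regions inside the background bins are therefore not the whole source. This does not exclude bound chromatin too weak to be called. X needed a higher fold for a call, so more of it could remain in such bins on X. Collapse of tags with a shared position lowers the denser autosomes more. Yet with all tags kept the ratio in bins at least 5 kb from any region was 0.553 (0.543 to 0.563) and 0.60 (0.592 to 0.608). Uncalled bound chromatin, and differences in mappability or base composition between X and autosomes or in the cells of the tissue, stay open and were not tested.

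A hypothesis from these data was that H3K4me3 and Pol II extend from a Pol II summit in 1 direction. The tests left it open. Of 3970 summits in H3K4me3 regions with at least a 2-fold difference in H3K4me3 between the sides, 62.9% (61.3 to 64.4) had more Pol II 1 to 3 kb away on the side with more H3K4me3. Places 5 kb or more from any region gave 53.9% (52.4 to 55.4), on far fewer H3K4me3 tags. With the tags around the summits thinned to the numbers around those places, the summits gave 61.2% (59.6 to 62.7). The difference from those places is therefore not a matter of tag number alone. Those places were chosen away from any region and need not be as uneven as the surroundings of summits. Uneven tag density common to both libraries was thus not excluded. Separate H3K4me3 regions nearby are not the whole source, since summits with 1 H3K4me3 region within 5 kb gave 70.9% (68.2 to 73.5). Neighbouring peaks joined into that 1 region, and neighbouring Pol II regions, were not left out by this choice and stay open. The general relation of Pol II to H3K4me3 at the same place may account for the shared side. Where H3K4me3 at 1 to 3 kb was not higher on the side with more H3K4me3 near the summit, the share was 28.9% (26.4 to 31.5) of 1222 summits, so Pol II there went with the H3K4me3 of its own place. The direction of genes was not used.

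A few positions held very many identical tags in both libraries. On U the minus strand tag starting at 9171006 was found 655 times with H3K4me3 and 456 times with Pol II, and on X that at 20252088 was found 475 and 409 times. Each counted as 1 tag in the results above.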
